A study of Mus musculus with 104 samples.

How the data were processed

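The samples were 104 HTGTS experiments from mouse ESC of 2 lines and NPC differentiated from them, with a bait on chromosome 7, 12 or 15, treated with APH or DMSO. Libraries were made by linear amplification-mediated PCR, per the labels' protocols. Reads were aligned with Bowtie2 to the mm9 genome, per the submitters' processing notes, and the versions, the junction caller and any down-sampling are not given in the sources used here. The deposited tables hold 1 junction read per row with its position, strand and bait alignment, so the values used are raw junction counts, per the file headers; they carry no normalization. There were 24 tables, 1 for each cell type, line, bait and treatment. The last column of each gives the experiment letter. In 21 tables the letters matched the labels. The other 3 (NPC line 2 bait 15 APH, ESC line 1 bait 7 DMSO and ESC line 2 bait 7 DMSO) had letters that did not match and were used as pools only. The filter columns of the tables (mapping quality, break site, sequential, repeat, duplicate) held 0 in every row, except in NPC line 2 bait 15 APH. There 33961 rows carried other or blank entries, and these rows were kept. The rows without an experiment letter in NPC line 2 bait 15 APH also numbered 33961. The mapping quality column is a flag and not a score, so a threshold on mapping quality was not applied.

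The tables held 2037403 rows. In NPC line 2 bait 12 APH and in ESC line 1 bait 7 APH, the reads of some experiments were listed again under another letter; each read name was counted once per table, which removed 18609 rows and left 2018794 junctions. The bait break was placed at the most frequent start of the bait alignment: 80451956 on chromosome 7, 13000729 on chromosome 12 and 86848129 on chromosome 15. Junctions within 5 Mb of a pool's own bait break were left out, as were the 63 bins within 5 Mb of any bait break and 509 junctions outside chromosomes 1 to 19 and X. The rest were counted in 500 kb bins, either strand, of which 5084 held a junction.

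The tests had been laid out for genes of 100 kb or more before the data were examined. The only annotation at hand is of another build than mm9, and coordinates were not converted, so the same tests were run on 500 kb bins; bins had been planned for the APH effects in ESC and NPC, and the other comparisons were moved to bins after the files were seen. Counts per gene, the fixed gene lists and the share of junctions in long genes were not analysed here. Bins were kept by filterByExpr with 4 groups and a minimum count of 5, which left 882, of which 415 lay on chromosomes 7, 12 and 15. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest, TMM normalization) on all 24 pools, with Benjamini-Hochberg adjustment at 0.05. APH effects came from a model with a block for each cell type, line and bait (12 blocks) and an APH term per cell type, and the difference between the cell types was the difference of these terms. NPC were compared with ESC within each treatment by a model with 6 line and bait blocks and the 4 conditions. Pools of the same line and bait come from the same cell line and break; the deviations of the APH and DMSO pools from their condition means correlated at 0.372 to 0.485 in ESC and 0.543 to 0.77 in NPC over the 6 pairs each. With the same bait in the other line they correlated at 0.345 to 0.393 in ESC and up to 0.817 in NPC, below the own pair in 6 of 6 ESC and 3 of 6 NPC pairs. In 10 of the 12 blocks, APH and DMSO pools were read in the same sequencing runs, going by the read names. Up to 20 bins per comparison were named by smallest adjusted p among those past the threshold with the same sign in both lines, with up to 5 that changed the opposite way, and the 5 with the smallest p where fewer than 5 passed; the text gives values for part of these.

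Shares of junctions were compared by exact sign-flip tests over the 6 line and bait pairs, two-sided, with 95% Clopper-Pearson intervals for single pools (scipy 1.17.1). Sequencing reads without molecular identifiers are not independent molecules. CPM values use TMM-scaled library sizes.

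The test was tried on simulated counts drawn from the real means and library sizes, with the spread fitted in the model of the APH effects and 200 of the 882 bins changed. It recovered 8% of 2-fold and 60% of 4-fold changes for APH in ESC, 49% and 99% for APH in NPC, 6% and 31% for the difference between the cell types, 32% and 95% for NPC against ESC under APH, and 26% and 89% under DMSO. Of the calls, 0, 1.99, 0, 3.79 and 6.50% were unchanged bins. For NPC against ESC the simulated means were set per line and bait alone. Variation of the cell type difference between lines and baits was therefore left out, so those rates may look better than the real data allow.

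Alternatives set before the data were examined were 250 kb and 1 Mb bins, total junctions off the bait chromosome as library size, no block and each line left out, for the APH effects. For the bait chromosome share, leaving out the 5 Mb zone and counting each position once were set in advance too, as was no filter for the correlation of the lines. Added for bins after seeing the data, most of them planned for genes, were the same settings for the other comparisons and, for all tests of bins, no filter, a 1 Mb zone, each position and strand once, only the compared pools, bait chromosome bins without that bait's pools, DESeq2 1.42.0, single lettered experiments, each bait or pair left out, and NPC pools thinned to ESC depth, with the same filter or with the filter redone.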

Results

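DNA break junctions were mapped by high-throughput genome-wide translocation sequencing (HTGTS), in which a double-strand break at a fixed bait site is joined to breaks elsewhere in the genome. The joined sequence is amplified from the bait and sequenced. The cells were mouse embryonic stem cells (ESC) of 2 lines and neural progenitor cells differentiated from them (NPC), lacking Xrcc4, a factor of end joining, and the tumour suppressor p53. Cells carried the bait on chromosome 7, 12 or 15 and were treated with aphidicolin (APH), an inhibitor of the replicative DNA polymerases that slows replication forks, or with its solvent DMSO. The 104 experiments were held in 24 pools, 1 for each cell type, line, bait and treatment, so that each of the 4 conditions had 6 pools. The pools held 2018794 junctions. ESC pools held 40544 to 82714 junctions under APH and 32896 to 113936 under DMSO, and NPC pools held 57231 to 211923 and 64048 to 152481. Outside 5 Mb around the bait break, ESC pools kept 4669 to 12786 junctions and NPC pools 12421 to 87885. The regions below are 500 kb bins in mm9 coordinates, and no gene was assigned to them. The labels do not say that the pools of one line came from separate cultures, so the p-values measure the spread between these pools, which may be partly technical.

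Most junctions lay on the chromosome that carried the bait, and more so in ESC than in NPC. The bait chromosome held 88.1% ± 3.68 of junctions in ESC and 70.5% ± 6.11 in NPC under APH (SD, n = 6 pools each), and 88.7% ± 3.88 and 76.8% ± 8.21 under DMSO. NPC lay below ESC in 6 of 6 line and bait pairs under APH, by a mean of -17.6 percentage points, and in 6 of 6 under DMSO, by -11.9 points. The exact paired permutation test, two-sided, gave p = 0.0312 for each, the smallest that 6 pairs allow, and 0.0391 adjusted over the 5 comparisons. APH lowered the share in 6 of 6 NPC pairs, by a mean of -6.30 points ± 2.26 (SD; exact test, p = 0.0312). In ESC the difference was -0.60 points ± 1.26, and 4 of 6 pairs were lower (exact test, p = 0.344). The APH effect differed between the cell types by -5.70 points ± 1.87 (exact test, p = 0.0312). Both the APH effect in NPC and this difference depended on which junctions were counted. Without junctions within 5 Mb of the break, the share was higher with APH in 6 of 6 pairs in NPC, by 3.16 points, and in 6 of 6 in ESC, by 1.81 points (exact test, p = 0.0312 for each, adjusted 0.0781). The APH effects then differed by 1.35 points (exact test, p = 0.375). NPC differed from ESC by -0.21 points under APH and -1.56 under DMSO (exact test, p = 0.594 and 0.219). With each position and strand counted once, these differences were -18.6 and -18.1 points, lower in 6 of 6 pairs in each (exact test, p = 0.0312 for each, adjusted 0.0781). The APH effect was then 1.00 points in NPC and 1.5 in ESC, and the difference between them -0.50 points (exact test, p = 0.531, 0.312 and 0.844). A single sequencing run read both cell types of the same line and bait (line 1, bait on chromosome 15). There the share under APH was 86.6% in ESC (95% Clopper-Pearson interval 86.2 to 87.0) and 63.4% in NPC (63.2 to 63.6). Under DMSO it was 85.0% (84.6 to 85.4) and 66.7% (66.4 to 67.0). These intervals cover counting error only.

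**Figure D1:**
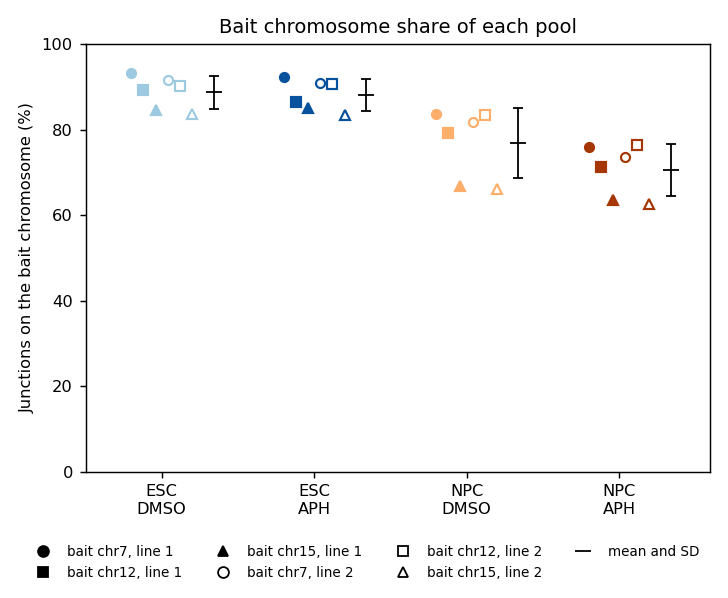
Share of junctions on the bait chromosome (y axis, %) for each pool, by cell type and treatment (x axis). Symbols give the bait and fill gives the line; the bar beside each group is the mean and SD of 6 pools. NPC pools treated with APH lie between 62.5 and 76.3%, below all ESC pools, which lie between 83.3 and 93.2%.

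The first question was whether ESC hold recurrent break clusters under replication stress. In ESC, 20 of the 882 tested bins gained junctions with APH and 0 lost them (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 87 bins, and with DESeq2 11 gained and 0 lost. The 20 edgeR bins formed 18 separate regions on 9 chromosomes. Together they held 3.48% of the junctions outside the bait zone in APH-treated ESC (1737 of 49912, 95% Clopper-Pearson interval 3.32 to 3.64) against 0.584% in DMSO (243 of 41596, 0.513 to 0.662). Single pools held 1.83 to 5.37% under APH and 0.343 to 0.825% under DMSO. Single experiments varied within pools. Under APH, experiment A of line 2 bait 7 held 0.571% (10 of 1752, 0.274 to 1.05) and B to D 2.11 to 2.26%, and A and B of line 1 bait 7 held 0.377 and 0.449% (2 of 530 and 2 of 445) and C to H 1.24 to 3.67%. Mislabelled or mixed experiments were not excluded in ESC, so these values hold for the labels as given. These intervals, and those for NPC, are on summed pools and cover counting error only, and the bins were picked for having risen. The smallest p-values were on chromosome 5, from 132.0 to 133.0 Mb, where both bins rose in 6 of 6 pairs. The bin from 132.5 Mb went from 344 ± 345 to 3859 ± 2089 CPM (depth-normalised junction count; SD, n = 6), a log2 fold change of 3.49 ± 0.49 (SE; edgeR adjusted p = 7.5e-10). The bin from 132.0 Mb changed by 3.24 ± 0.48. The chromosome 8 bin at 117.0 to 117.5 Mb reached the highest level under APH among these. It rose from 849 ± 811 to 5457 ± 2511 CPM (log2 fold change 2.88 ± 0.44, edgeR adjusted p = 2.21e-08). Its neighbour up to 118.0 Mb rose by 1.68 ± 0.45. Chromosome 12 gave 6 bins, with log2 fold changes of 3.16 at 35.0 Mb, 3.04 at 38.5 Mb, 3.11 at 42.5 Mb, 2.16 at 51.5 Mb, 2.27 at 55.5 Mb and 2.00 at 79.5 Mb. The bait on that chromosome gave 61.5 to 83.2% of their depth-scaled junctions, and the bin at 79.5 Mb was higher in 3 of 6 pairs. Chromosome 15 gave bins at 30, 32 and 68.0 Mb, with 2.07, 1.75 and 2.05. At 32 Mb, 1 pool (line 2 bait 15) had 3326 CPM under APH while the other 5 reached at most 851. The others lay on chromosome 1 at 25.5 Mb (2.67), chromosome 3 at 55.5 Mb (2.36), chromosome 7 at 25.0 Mb (2.53) and chromosome 8 at 129.5 Mb (1.93). Further ones lay on chromosome 14 at 10.5 and 117.5 Mb (1.99 and 2.70) and chromosome 16 at 24.5 Mb (3.45). Within these bins the junctions of all 24 pools together were spread out: the busiest 1 kb held 1.22 to 4.80% of a bin's junctions. Shares in 1 kb and depth-scaled shares of baits, here and below, count the pools of both cell types and treatments. In these bins NPC pools held 4213 junctions under APH and 1551 under DMSO, against 1737 and 243 in ESC. The shares therefore do not give the shape in ESC alone. Of the 20 bins, 10 lay on a bait chromosome, and 10 bins in all passed when such bins were tested without that bait's pools. Fewer bins passed without line 1 (3) or line 2 (8), without bait 12 (7) or bait 15 (12), without line 1 bait 12 (7) or line 2 bait 12 (11), and without the line and bait block (3). The count was 10 in 1 Mb bins and 13 with no filter. These are counts of all bins that passed, not only of the 20. Without bait 12, 6 gained and 1 lost junctions, and without line 2 bait 12, 10 gained and 1 lost. Without line 2, 7 of the 8 were among the 20.

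In NPC, APH raised junctions in 71 bins and lowered them in 3 (same test). The 71 bins formed 54 regions on 19 chromosomes, 16 of them of 2 or more adjoining bins. They held 7.51% of the junctions outside the bait zone under APH (20156 of 268280, 7.41 to 7.61; single pools 5.38 to 10.9%) against 3.10% under DMSO (5130 of 165370, 3.02 to 3.19). The DMSO pool of line 2 bait 15 stood apart, with 5.06% (2941 of 58101, 4.89 to 5.24), close to the 5.38% of its APH pool. The other 5 DMSO pools held 1.44 to 2.78%, together 2.04% (2189 of 107269, 1.96 to 2.13). In the pool that stood apart, experiments A and D held 8.26 and 5.98%, and B and C 1.47 and 1.49%. Experiments B of line 1 bait 12 (5.68%) and C of line 1 bait 7 (4.27%) under DMSO were high as well, while the other 20 DMSO experiments of NPC held 1.33 to 2.58%. All experiments were used as labelled, and mislabelled or mixed ones were not excluded, so the NPC values under DMSO and the folds against them hold for the labels as given. The smallest p belonged to chromosome 10 at 32 to 32.5 Mb, which rose from 189 ± 213 to 1148 ± 591 CPM (SD, n = 6) in 6 of 6 pairs. Its log2 fold change was 2.23 ± 0.37 (SE; edgeR adjusted p = 2.01e-06), and its neighbour from 31.5 Mb changed by 1.62. Chromosome 3 at 24 Mb rose from 420 ± 462 to 1757 ± 525 CPM (2.16 ± 0.37) and at 24.5 Mb by 1.74. Chromosome 14 at 39.5 Mb rose from 519 ± 433 to 2211 ± 859 CPM (2.14 ± 0.37). Chromosome 5 at 19.0 Mb rose from 435 ± 391 to 1844 ± 558 CPM (2.12 ± 0.37). Chromosome 16 at 6.5 Mb rose from 564 ± 598 to 2188 ± 729 CPM (2.14 ± 0.38), and chromosome 19 at 31.0 Mb from 713 ± 624 to 2491 ± 934 CPM (1.93 ± 0.37). Without the DMSO pool of line 2 bait 15, the DMSO means of the 6 bins with CPM values were 129 ± 174, 268 ± 307, 365 ± 237, 286 ± 160, 325 ± 142 and 470 ± 215 CPM, in the order given (SD, n = 5), so that pool raised them 1.42 to 1.73 times. Over the 20 named bins that rose, that pool changed the DMSO mean 0.876 to 2.37 times, by 1.5 times or more in 8 bins. The largest change was on the X chromosome at 117.5 Mb, where the mean was 159 ± 231 CPM with the pool and 66.9 ± 59.6 without it, and chromosome 3 at 24.5 Mb moved 1.68 times. Chromosome 6 held 3 of the named bins, at 61.5, 63.5 and 77.0 Mb, with log2 fold changes of 1.83, 1.75 and 2.04. Further rises were seen on chromosome 8 at 16.5 Mb (1.82) and 121.0 Mb (1.66), chromosome 10 at 49.0 Mb (1.70), and chromosome 12 at 67.5 Mb (1.95). The remaining named rises were on chromosome 18 at 25.0 Mb (1.63), chromosome 4 at 65.0 Mb (1.68), chromosome 7 at 98.0 Mb (1.84), chromosome 1 at 68.5 Mb (1.57) and the X chromosome at 117.5 Mb (1.86). The 3 bins that fell were on chromosome 13 at 54 Mb (-1.41 ± 0.38), chromosome 11 at 116.0 Mb (-1.23 ± 0.36) and chromosome 7 at 149.5 Mb (-1.21 ± 0.36), each lower in 6 of 6 pairs. Over all 24 pools, junctions in the 71 bins were spread out as well, with at most 6.37% in the busiest 1 kb. Without line 1, 0 bins passed with edgeR (51 at an unadjusted p under 0.05), against 91 without line 2. The 73 bins that rose in line 1 tested alone were all higher in line 2 as well, by a median log2 fold change of 1.19. The count was 36 without bait 7, 32 without bait 12, 47, 41 and 40 without the line 1 pairs of baits 7, 12 and 15, and 112 without line 2 bait 15. It was 39 in 250 kb bins and 0 without the line and bait block (63 at an unadjusted p under 0.05). With NPC pools thinned to ESC depth it was a median of 36.5 (19 to 40 in 10 draws), and 21 with the filter redone in 1 draw. Single experiments gave more, as given below.

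**Figure D2:**
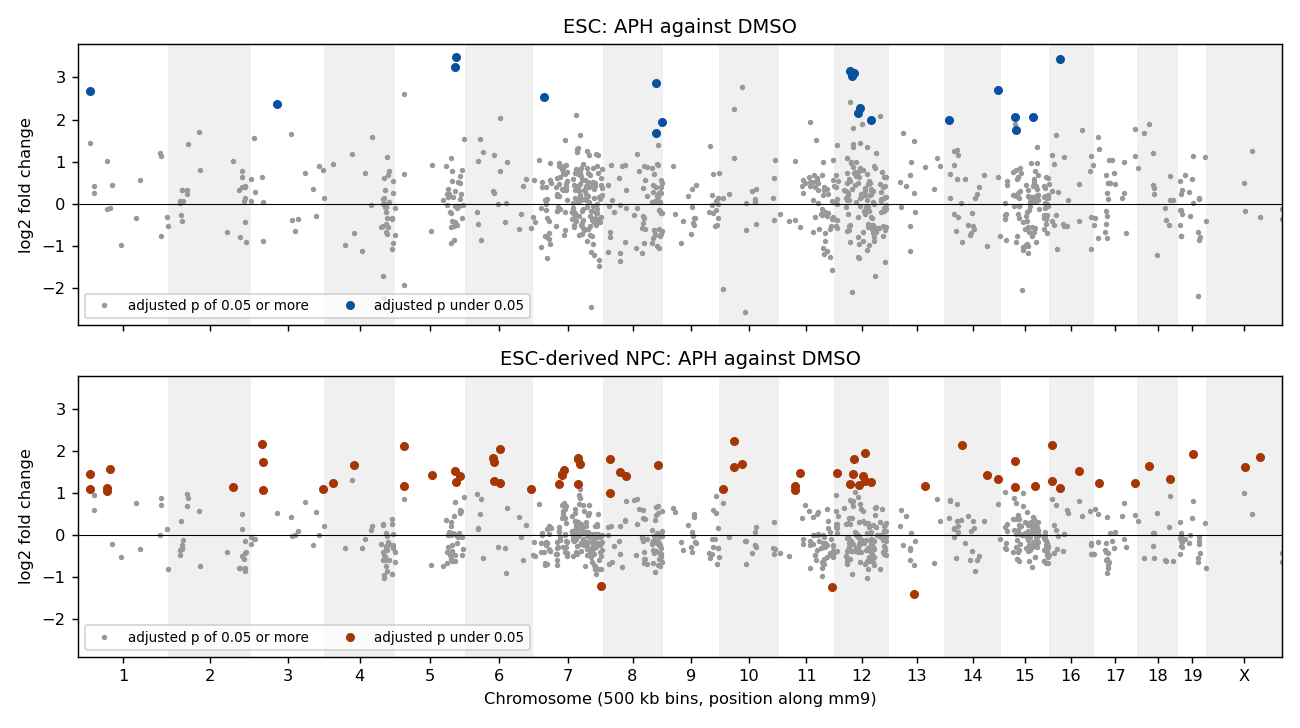
Log2 fold change of APH against DMSO (y axis) for each of the 882 tested 500 kb bins along the genome (x axis, chromosomes in mm9 order), in ESC (top) and NPC (bottom). Coloured points passed an adjusted p under 0.05: 20 higher in ESC, and 71 higher and 3 lower in NPC. The dense columns on chromosomes 7, 12 and 15 are the bait chromosomes, where more bins reached the count minimum.

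The ESC and NPC gains overlapped in part. They had 9 bins in common, against 1.61 if the lists were independent (Fisher's exact test, two-sided, p = 7.07e-06). The comparisons have no pool in common, but both come from the same fit, which shares the spread of each bin between the cell types. Bins with more junctions or less spread are easier to call in both. The expected number takes all bins as independent and equally easy to call, and adjoining bins were counted apart. The overlap may therefore look less likely by chance than it is. The common bins were chromosome 5 at 132.0 and 132.5 Mb, chromosome 12 at 35.0, 42.5 and 79.5 Mb, chromosome 1 at 25.5 Mb, chromosome 14 at 117.5 Mb, chromosome 15 at 30 Mb and chromosome 16 at 24.5 Mb. Of the 11 bins called in ESC and not in NPC, 9 had a positive fold change in NPC, and of the 62 called in NPC and not in ESC, 45 had one in ESC. When the difference between the APH effects was itself tested, 0 bins passed with edgeR (66 at an unadjusted p under 0.05) and 0 with DESeq2 (65 unadjusted). No single bin was shown to respond to APH in one cell type more than in the other. The 5 bins with the smallest p did not pass. Chromosome 8 at 117.0 Mb (log2 difference, NPC minus ESC, -2.20 ± 0.59 SE), chromosome 11 at 68.0 Mb (-2.73 ± 0.75), chromosome 7 at 25.0 Mb (-2.92 ± 0.82) and chromosome 5 at 132.5 Mb (-2.22 ± 0.63) leaned to ESC, each with an edgeR adjusted p of 0.103. Chromosome 14 at 39.5 Mb (3.05 ± 0.95) leaned to NPC, with 0.225. On simulated counts the test of the difference recovered 31% of bins changed 4-fold. There 200 of the 882 bins were changed, and only in the APH-treated NPC pools. With fewer changed bins the adjusted threshold is stricter, so the rate may be lower. Changes in the shallower ESC pools were not simulated for this test. The count was 1 in 1 Mb bins and 1 without line 2 bait 7, and single lettered experiments gave 5 bins, and 1 with the letter as a block. The settings with single experiments counted experiments of the same pool as replicates. They also left out bait 7 in ESC and line 2 bait 15 in NPC, where letters did not match.

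Across the 882 bins, the APH fold changes of line 1 and line 2 correlated at Pearson r = 0.65 (Spearman 0.55) in NPC and at 0.17 (Spearman 0.13) in ESC. With no filter, over 5084 bins, Pearson r was 0.246 in NPC and 0.059 in ESC, so the size of the correlation depended on the filter. With the filter, the permutation p was 1e-04 for each of the 4, the smallest the permutations can give. These are correlations across bins, which are not independent replicates. Tested alone, line 1 gave 75 bins in NPC and 9 in ESC, and line 2 gave 0 and 3, of which 3 ESC bins were called in both.

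**Figure D3:**
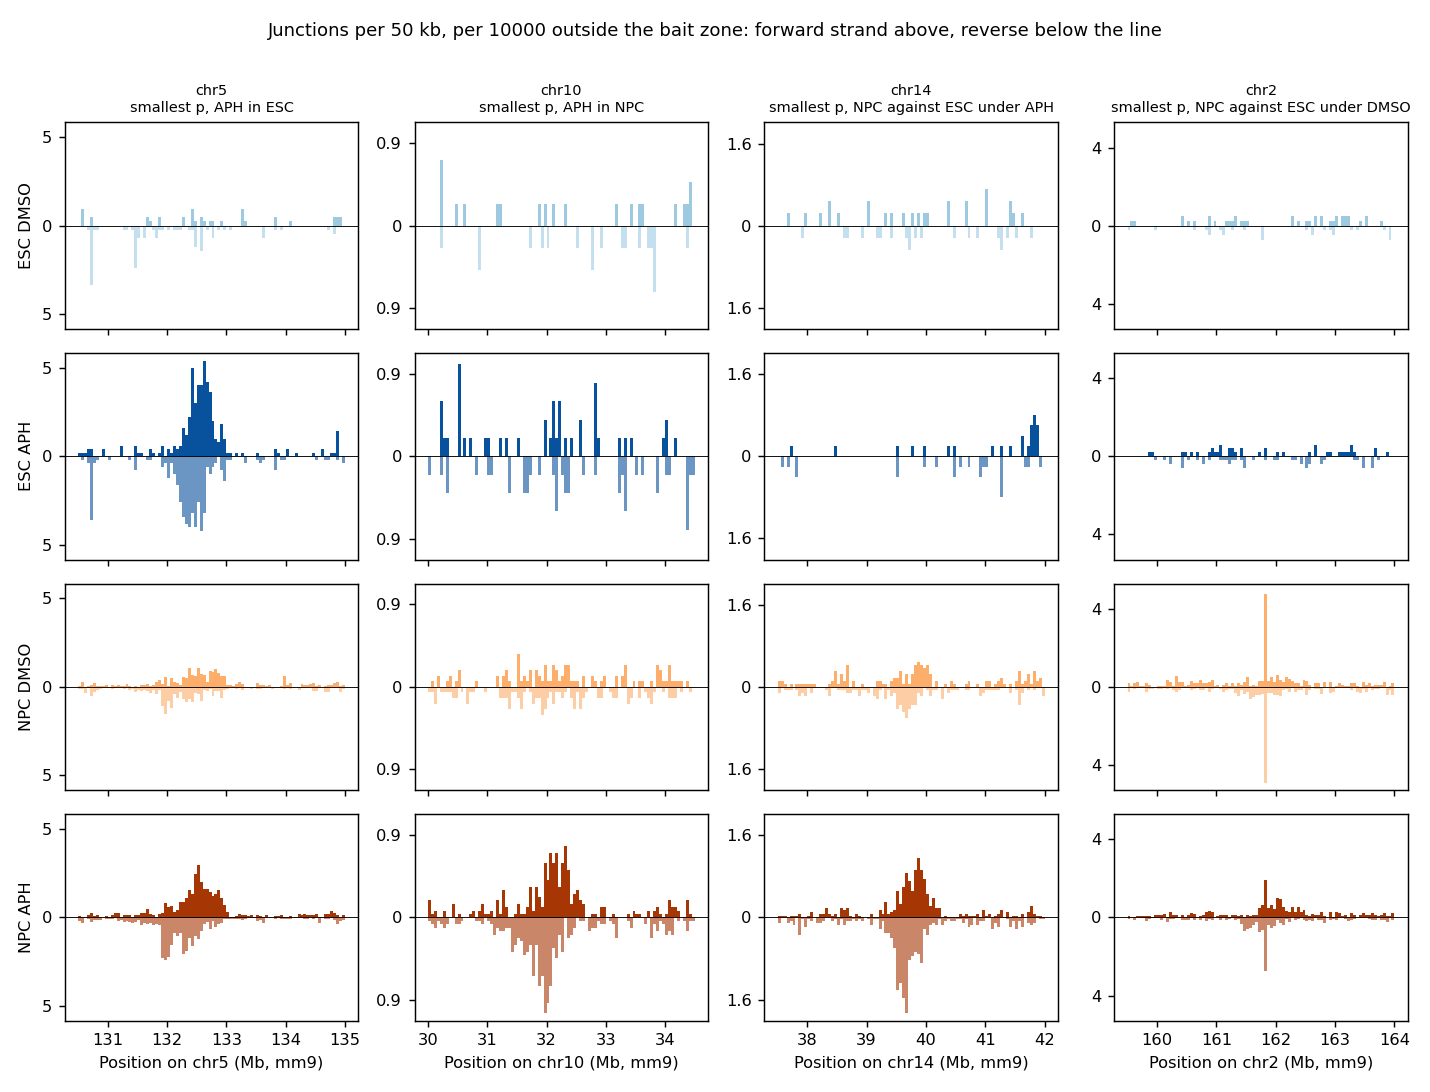
Junctions per 50 kb, per 10000 outside the bait zone (y axis; forward strand above the line, reverse below), within 2 Mb of the bin with the smallest p in each of 4 comparisons (columns; x axis, position in Mb), in the 4 conditions (rows). The chromosome 5, 10 and 14 regions are broad under APH, whereas the chromosome 2 region has a narrow peak in NPC. Over all pools, 32.1% of the junctions of that chromosome 2 bin lay in 1 kb.

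Under APH, NPC and ESC differed in 151 bins, 120 higher in NPC and 31 lower (edgeR, adjusted p under 0.05), as shares of junctions. With NPC pools thinned to ESC depth the total was a median of 98.5 (90 to 105 in 10 draws), and 61 with the filter redone in 1 draw. It was 95 in 250 kb bins, and higher with single experiments, as given below. The bins higher in NPC were led by chromosome 14 at 39.5 Mb, with 2211 ± 859 CPM in NPC and 118 ± 104 in ESC (SD, n = 6 each; log2 fold change 4.38 ± 0.58, SE; edgeR adjusted p = 4.41e-11). Chromosome 8 at 16.5 Mb came next, with 1608 ± 568 against 73.6 ± 57.4 (4.41 ± 0.61). Chromosome 5 at 19.0 Mb (3.66), chromosome 16 at 6.5 Mb (3.42), chromosome 6 at 77.0 Mb (3.38), chromosome 3 at 24 Mb (3.45) and 24.5 Mb (3.59), chromosome 1 at 68.5 Mb (3.24) and the X chromosome at 117.5 Mb (4.14) and 84.5 Mb (3.88) followed, each higher in 6 of 6 pairs. Chromosome 7 at 103.5 Mb had the highest level, 6921 ± 8810 CPM in NPC against 1136 ± 1608 in ESC (2.58 ± 0.48), with 86.3% of its depth-scaled junctions from the bait on the same chromosome. Without line 1 bait 7 it was 4448 ± 7151 against 550 ± 808 (SD, n = 5 each). Bins higher in ESC were led by chromosome 3 at 55.5 Mb (-1.92 ± 0.38), which also rose with APH in ESC, and by chromosome 5 at 137.0 Mb (-2.24 ± 0.45) and chromosome 14 at 46.0 Mb (-2.14 ± 0.44), where 1 ESC pool (line 1 bait 15) reached 6528 and 3784 CPM. Chromosome 10 at 121.0 Mb (-1.90 ± 0.41) and chromosome 8 at 117.0 Mb followed (-1.83 ± 0.41; 1428 ± 283 CPM in NPC and 5457 ± 2511 in ESC). Of the 31 bins higher in ESC, 19 held 20% or more of their junctions in 1 kb, a limit set after the values were seen, against 9 of the 120 higher in NPC. With total junctions off the bait chromosome as the library size, the split was 90 higher and 56 lower. The median log2 fold change of all bins moved from 0.19 to -0.11 with it. The bins higher in ESC were fewer under several settings. Their number was 1 without line 1, 9 without line 2, 3 without bait 15, 16 without line 1 bait 15, and 4 without the line and bait block, beside 55, 95, 100, 96 and 55 higher in NPC. With DESeq2 it was 16, with no filter 14 and with each position and strand counted once 12, beside 148, 244 and 108. A sequencing run with both cell types was found for 1 of the 6 line and bait pairs, so cell type and run cannot be told apart.

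**Figure D4:**
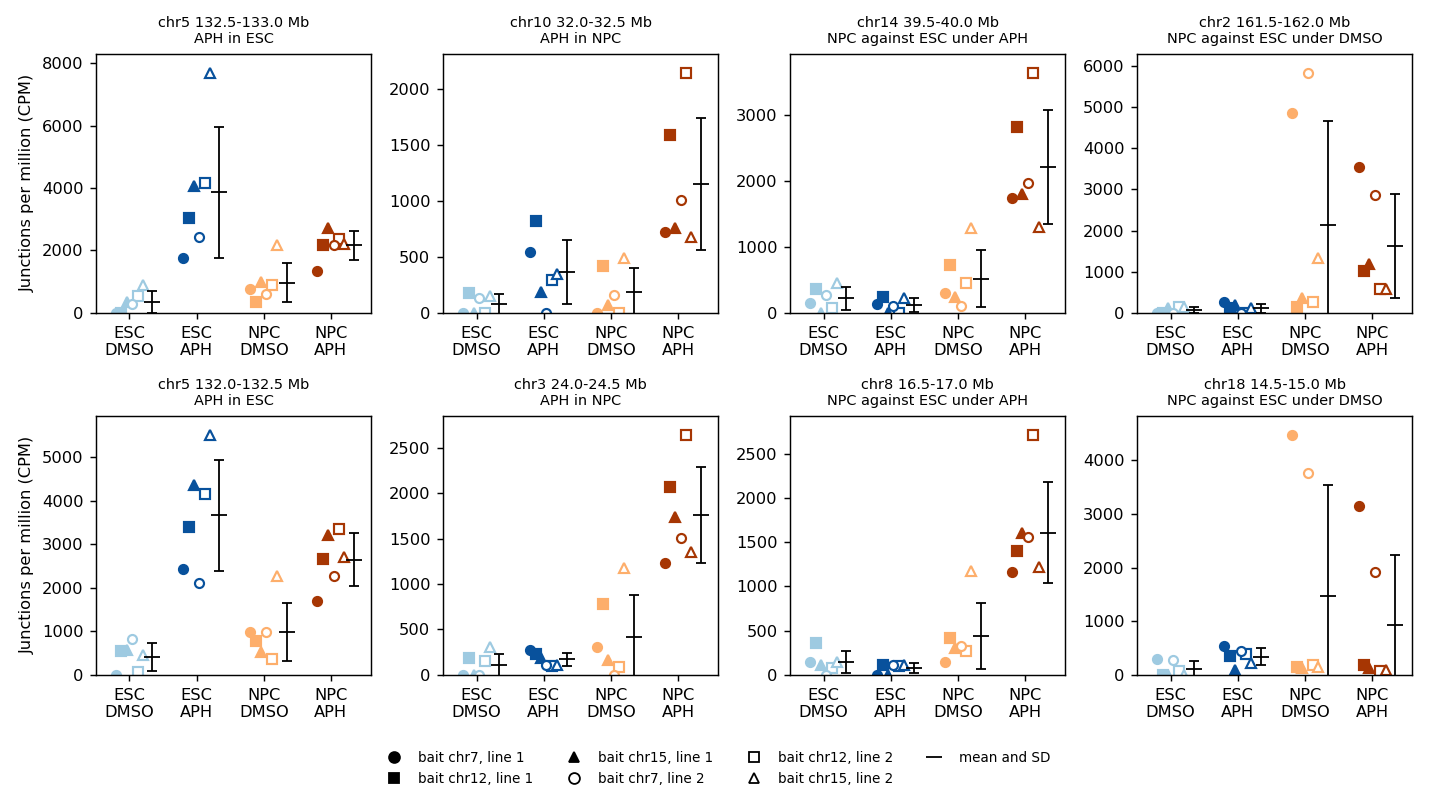
Depth-normalised junction counts (y axis, CPM) in each pool of the 4 conditions (x axis) for the 2 bins with the smallest p in each of 4 comparisons. Symbols give the bait, fill gives the line, and bars are the mean and SD of 6 pools, with lower ends cut off at 0. In the chromosome 2 and 18 bins the highest NPC values come from the chromosome 7 bait.

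Without added replication stress, fewer bins differed between the cell types: 14 were higher in NPC and 6 lower under DMSO (edgeR, adjusted p under 0.05). The total of 20 was a median of 4 (2 to 8 in 10 draws) with NPC pools thinned to ESC depth, and 2 with the filter redone after thinning. It was 4 with only the compared pools, with the filter redone on them, and 13 in 1 Mb bins. Single experiments gave 134, and 95 with the letter as a block. These refits counted experiments of the same pool as replicates, so their counts may be too high. They kept only line and bait pairs lettered in both treatments of both cell types. This left out all pools with bait 7 and those of line 2 bait 15. The bin with the smallest p was chromosome 2 at 161.5 Mb, with 2133 ± 2536 CPM in NPC and 70.1 ± 77.9 in ESC (SD, n = 6 each; log2 fold change 3.99 ± 0.69, SE; edgeR adjusted p = 5.35e-06). The NPC mean rested on the 2 pools with bait 7, with 4847 and 5829 CPM in lines 1 and 2, while the other 4 held 156 to 1327. Without line 2 bait 7 it was 1394 ± 1986 (SD, n = 5). Chromosome 18 at 14.5 Mb followed, with 1475 ± 2056 against 109 ± 142 (3.32 ± 0.69). There the 2 bait 7 pools held 4468 and 3759 CPM and the other 4 NPC pools 134 to 181. Without line 1 bait 7 the means were 876 ± 1612 and 70.4 ± 119 (SD, n = 5 each). Others higher in NPC were chromosome 5 at 19.5 Mb (3.27), chromosome 19 at 30.5 Mb (3.37), and chromosome 14 at 70.5 Mb (2.51). So were chromosome 2 at 41.0 and 162.0 Mb (3.08 and 2.94), chromosome 10 at 49.0 Mb (3.43) and chromosome 16 at 6.0 and 92.5 Mb (2.16 and 2.17). The NPC line 2 bait 15 pool, where mislabelled or mixed experiments were not excluded, stood highest in some of these. It held 542 CPM on chromosome 10 at 49.0 Mb, with the other NPC pools up to 227. On chromosome 16 at 6.0 Mb it held 1065 (others up to 571), and on chromosome 5 at 19.5 Mb 1289 (others up to 682). It was highest by less on chromosome 19 at 30.5 Mb and chromosome 2 at 41.0 and 162.0 Mb, and not highest in the others named. Bins higher in ESC were led by chromosome 7 at 35.5 Mb (-1.89 ± 0.46) and chromosome 13 at 45.0 Mb (-1.87 ± 0.46). They were followed by chromosome 16 at 31.5 Mb (-1.85, although 4 of 6 pairs were higher in NPC), chromosome 5 at 137.0 Mb (-1.72) and chromosome 2 at 169.5 Mb (-1.71). Of the 20 bins, 9 held 20% or more of their junctions in 1 kb: 4 of the 14 higher in NPC and 5 of the 6 higher in ESC, against 66 of all 882 tested. In the 4 higher in NPC, 1 bait gave 99.5 to 100% of the depth-scaled junctions of that kilobase, at 46 to 112 positions (strands counted apart). In the 5 higher in ESC the highest bait gave 51.9 to 100%, at 7 to 17 positions, with 94.0 to 100% on 1 strand. On chromosome 18 the kilobase from 14713001 to 14714000 held 58.7% of its bin, and 89.7% of that bin's depth-scaled junctions came from the chromosome 7 bait. With total junctions off the bait chromosome as the library size, 5 bins were higher and 9 lower in NPC, and the median log2 fold change of all bins moved from 0.33 to -0.10. Without line 1 or without line 2, 0 bins passed (edgeR, 78 and 98 at an unadjusted p under 0.05), and 2 passed without the line and bait block. The count was 9 with DESeq2, 9 without bait 7, 9 without bait 15, 11 without line 2 bait 7, 10 without line 2 bait 15 and 36 without line 2 bait 12. Of the 10 without line 2 bait 15, 7 were among the 20.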

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

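All tests of explanations in this part were chosen after the results were seen.

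Swapping labels within the 6 line and bait pairs gave 32 splits for each comparison. The real labels gave more called bins than any other split for APH in ESC (20, highest other 11), APH in NPC (74, highest other 71), NPC against ESC under APH (151, highest other 53) and under DMSO (20, highest other 6). So 1 of 32 splits, the real one, was as large in each. This is the smallest share that 32 splits can give, and it was not adjusted over the comparisons. It makes chance unlikely for each comparison taken alone, but does not exclude it. In NPC, the split with 71 calls swapped line 2 bait 15 alone, and 112 bins passed without that pair. For the difference in APH effect the real count was 0, which all 32 splits reach by definition (highest other 5), so the splits say nothing about chance there.

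More bins rose with APH in NPC than in ESC, and NPC pools were deeper. With NPC pools thinned to the ESC pool of the same line, bait and treatment, NPC calls fell from 74 to a median of 36.5 (19 to 40) and still exceeded the ESC calls of the same fit (13 to 17) in 10 of 10 draws (with the count filter redone in 1 draw, NPC gave 21 and ESC 9). Depth therefore accounts for part of the excess, and the tables argue against depth as the whole cause. Among the 73 bins that rose in NPC line 1, 49 had a larger fold change in NPC than in ESC in line 2. The medians there were log2 1.19 and 0.60 (exact sign test, p = 0.00463). All 9 bins that rose in ESC line 1 were larger in ESC in line 2 (exact sign test, p = 0.00391). Both tests take bins as independent. Line 2 took no part in the picking, so this goes with APH effects that differ by cell type at these bins. The lists went opposite ways, so whether a larger APH effect in NPC explains the excess stays open. The NPC folds of line 2 include bait 15. Its DMSO pool held 5.06% of its junctions outside the bait zone in the bins that rose in NPC, close to 5.38% under APH. No single bin passed the test of the difference, and cell type and sequencing run stay open.

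Bins that differed between the cell types under DMSO were often narrow. Of the 20, 9 held 20% or more of their junctions in 1 kb (4 of 14 higher in NPC, 5 of 6 higher in ESC, 66 of 882 tested; this limit was set after the values were seen), against 0 of the 71 changed by APH in NPC and not called under DMSO. For the bins higher in NPC, a site cut by the nuclease of 1 bait is a candidate explanation. In 4 of 4, 1 bait gave 99.5 to 100% of the depth-scaled junctions of the busiest 1 kb. Pools with the same bait held 0 to 8 of these junctions in ESC and 101 to 466 in NPC, where pools were deeper. Outside the bait zone, bait 7 had 24996 junctions in ESC and 88933 in NPC, and bait 15 had 32191 and 250162. Depth thus accounts for part of the gap, and the cause of the rest stays open. In 3 of the 5 bins higher in ESC, 2, 8 and 11 pools with other baits had junctions there, at 7, 11 and 13 positions, above their rate in the rest of the bin with each position counted once per pool, which argues against such a site as the cause for all 5. Whether these are fragile, repeated or wrongly aligned sequence stays open.

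The APH effect on the bait chromosome share differed between NPC and ESC by -5.695 percentage points (exact paired permutation test, p = 0.0312), and by 1.35 (p = 0.375) without the 5 Mb zone. The comparisons of bins leave out junctions near any bait break, while the bait chromosome share counts them. Junctions within 1 kb of the chromosome 12 bait break appeared in 10 of the 16 pools with another bait, 780 in all, with 577 in NPC line 2 bait 15 APH, against 12 in its DMSO pool. Per 10000 junctions off the bait chromosome this pool had 98.0, and ESC line 2 bait 15 DMSO had more, 122, from 66 junctions. No such junction was seen at the chromosome 15 break in 16 pools, and 28 at the chromosome 7 break.

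Pools that stood apart from the other 5 of their condition were looked for in 97 sets of 6 pools, and 9 were found. The limit used gives about 1 in 20 by chance for independent, normally distributed sets. Most sets here were CPM values of bins named for a change, from the same pools. The chance rate is therefore not known, and 9 was not shown to exceed it. ESC line 2 bait 12 DMSO held 113936 junctions, the others 32896 to 53859. ESC line 2 bait 15 APH had 3326 CPM at chromosome 15, 32 Mb (others up to 851). ESC line 1 bait 15 APH had 6528 CPM at chromosome 5, 137.0 Mb (others up to 2102) and 3784 at chromosome 14, 46.0 Mb (others up to 1327). NPC line 2 bait 12 APH had 2709 CPM at chromosome 8, 16.5 Mb (others up to 1604). NPC line 1 bait 7 DMSO had 1590 at chromosome 7, 149.5 Mb (others up to 708), and NPC line 2 bait 15 DMSO had 541.9 at chromosome 10, 49.0 Mb (others up to 227). The last pool also held 5.062% of its junctions in the 71 bins that rose in NPC (others 1.44 to 2.78%) and 1.413% in the 20 that rose in ESC, whose fold changes came from ESC pools alone (others 0.572 to 0.773%), near its APH pool (5.38 and 1.38%). The 71 bins held 1.85% of the 12865 junctions without a letter in that APH pool, and 6.53 and 5.99% of those lettered B and D. That APH pool held 65439 junctions outside the bait zone. Its rows without a letter equal in number those with other or blank filter entries, 33961 each before the zone was left out. In ESC, experiment A of line 2 bait 7 APH held 1.60% in the 71 bins (B to D 3.61 to 4.82%), A of line 2 bait 15 DMSO 3.07% (B to D 0.753 to 1.43%), and G of line 1 bait 7 DMSO, a table whose letters did not match, 4.59% (its other letters up to 1.78%). These shares do not tell a mislabelled or mixed experiment from a real difference between experiments, so both stay open in both cell types.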

How the results depend on the processing

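The settings for bins named in the methods as added, and the leave-out of pairs for the shares, were chosen after seeing the data. No named bin changed direction under any of the settings run for bins, but calls were lost in 160 of 454 refits of named bins for APH in ESC, 80 of 544 in NPC, 13 of 601 for NPC against ESC under APH and 196 of 415 under DMSO. In the order APH in ESC, APH in NPC, NPC against ESC under APH, and under DMSO, the counts of 20, 74, 151 and 20 became 3, 0, 59 and 2 without the line and bait block. Single experiments gave 44, 167, 278 and 134 without and 34, 144, 252 and 95 with the letter as a block. These refits left out blocks without matching letters: bait 7 in ESC and line 2 bait 15 in NPC. For NPC against ESC, both were left out in both cell types. Leaving out line 2 bait 15 alone gave 112 for APH in NPC. The pools used thus changed along with the unit that was counted. Over 36 letter pairs the deviations correlated at -0.115 to 0.146, 3 of them over 0.1, so letters do not pair experiments. Only the compared pools, with the count filter redone on them, gave 7 in ESC, 86 under APH and 4 under DMSO. The set of tested bins thus changed as well. NPC pools thinned to ESC depth gave 36.5, 98.5 and 4 (medians of 10 draws) for NPC, APH and DMSO, and with the filter redone in 1 draw (324 bins) 9, 21, 61 and 2 for the 4 in order. Bins of 250 kb gave 39 in NPC and 95 under APH, and 1 Mb bins 10 in ESC and 13 under DMSO. In ESC there were 13 with no filter, 11 with each position once, 10 without the bait's own pools and 11 with DESeq2; DESeq2 gave 9 under DMSO, and no filter 258 under APH. The difference in APH effect, 0 bins, gave 1 in 1 Mb bins, 5 for single experiments, 1 with the letter block and 2 with the filter redone after thinning. Leaving out lines, baits or pairs gave 3 to 18, 0 to 112, 56 to 143, 0 to 36 and, for the difference, 0 to 1. The total counts stayed within 1.5 times under the other settings. The causes were not tested.

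The APH effect on the bait chromosome share changed sign without the 5 Mb zone (1.81 points in ESC, 3.16 in NPC) and with each position once (1.5 and 1.00). NPC minus ESC was -0.21 points under APH and -1.56 under DMSO without the zone. With 1 pair left out, 5 pairs cannot reach 0.05 (smallest p 0.0625), and the effects were -0.843 to -0.149 in ESC, -6.90 to -5.94 in NPC, -18.3 to -16.8 under APH and -13.0 to -10.8 under DMSO. The correlation of the lines was 0.059 in ESC and 0.246 in NPC with no filter. Gene-level settings, gene lists, the share in long genes and a mapping quality threshold were planned and not run. On simulated counts 60% of 4-fold changes were recovered for APH in ESC and 31% for the difference; what depth, spread and the number of pools each contribute was not separated.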

Other observations

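The tests in this part were chosen after the results were seen. Inside the regions that gained junctions with APH, the strands were offset. In NPC, forward-strand junctions had a median position further along the chromosome than reverse-strand ones in 52 of 54 regions, by a median of 172 kb (APH pools with the bait on another chromosome, within 500 kb of the middle of the region; exact sign test, p = 1.65e-13). Bins with no APH effect showed it in 182 of 352, with a median of 4.08 kb (Fisher's exact test between the sets, p = 1.28e-11), which argues against an offset present at any bin. It was seen in 46 of 48, 42 of 46 and 51 of 52 regions with baits 7, 12 and 15, so the lowest share was 91.3%, which argues against one bait or its primer orientation as the source. In DMSO-treated NPC it was seen in 49 of 53 regions, with a median of 134 kb, and without the line 2 bait 15 pool in 32 of 44, with 74.1 kb. It was seen in ESC under APH in 10 of the 10 regions with at least 10 junctions per strand, by a median of 122 kb. The window and the minimum of 10 junctions per strand were set after a first look at single bins, and no biological explanation was tested.

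Bait and prey alignments overlapped by 1 base or more, as at microhomology, in more junctions of NPC than of ESC: 76.0% ± 0.499 against 63.9% ± 5.06 under APH and 76.4% ± 3.13 against 66.4% ± 5.08 under DMSO (SD, n = 6 pools, outside the 5 Mb zone). It was higher in 6 of 6 pairs in each (exact paired permutation test, p = 0.0312, and 0.0781 adjusted over 5 comparisons, so not past 0.05). In the run that read both cell types, the values were 65.0% in ESC and 75.6% in NPC under APH, and 70.3 and 78.1% under DMSO. Junctions with bases between the alignments were fewer in NPC, 17.2% ± 0.795 against 29.0% ± 5.73 under APH. Overlaps of 4 bases or more differed less, 25.0% ± 0.280 against 22.9% ± 2.97 (exact test, p = 0.188).

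In DMSO pools with the bait elsewhere, chromosome 8 held 1.31 and 1.48 times the median junctions per Mb of the chromosomes without a bait in ESC lines 1 and 2, and 1.44 and 1.48 times in NPC. Chromosome 8 was not alone: chromosome 11 held 1.14 and 1.16 times in ESC and 1.38 and 1.34 times in NPC. Chromosome 19 held 1.26 and 1.23 times in ESC and the same in NPC. The X chromosome held 0.511 and 0.539 times in ESC and 0.373 and 0.395 times in NPC. These densities were not corrected for chromosome copy number, so they do not measure breaks per copy.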
